A study of Mus musculus with 6 samples.

How the data were processed

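RNA was measured in 6 samples of olfactory epithelium (septa and turbinates) of newborn mice, 3 from Atf5 knockout and 3 from wild-type pups, each pooled from 3 pups. Per the labels' protocols, total RNA was extracted with Trizol and purified on Qiagen RNeasy columns, cDNA was made with the Ambion WT Expression Kit, and the product was fragmented and labelled with biotin by the Affymetrix WT terminal labelling kit, in 1 colour. Per the submitters' processing notes, RMA, affy and limma were used, without versions. RMA, as generally defined, corrects the background, quantile-normalizes probes across arrays and summarises probes per probe set. The values the authors deposited were read as log2 expression levels, since they ran from 4.50 to 14.7; the base of the logarithm and the order of steps are not given in the sources used here. Because quantile normalization gives all arrays nearly one distribution, a change shared by most transcripts is not visible in such values, and changes of dim probe sets may be compressed. Group and replicate number came from the sample titles. The series' labels describe biological replicates from separate pools of pups. No column of other samples was used (0 present).

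The table held 34760 rows. GEO's platform annotation gave 1 gene symbol for 21640 rows, several for 1321 and none for 11799. Rows with 1 symbol were used; 21553 of them had a gene number in the mouse reference table of assembly GRCm38.p6, which changed 0 symbols and was otherwise used only for synonyms, receptor naming and gene order. For the 954 genes with several probe sets, the one with the highest mean over all 6 arrays was taken, which left 19937 genes. Another 94 rows with several symbols name an olfactory receptor and were not counted as genes. No filter on dim probe sets was applied.

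Knockout was compared with wild type by limma 3.58.1 (lmFit and eBayes, no trend, no covariate) in R 4.3.3, on the log2 values as deposited, 2-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. An adjusted p without another name comes from this test. SE is limma's moderated standard error, and intervals of folds are at 95%. The 33 gene lists were fixed before the data were examined, as were the test, the alternatives and the naming rule. Lists with at least 5 measured members were tested by camera with a preset correlation of 0.01, 2-sided, adjusted over the 33 lists, and again with an estimated correlation and by fry. With the preset correlation 18 lists passed, with an estimated correlation 0 (smallest adjusted p = 0.0859), and by fry 8. Calls adjusted over the list alone used the same p-values with adjustment within the list. A few genes stand in more than 1 list (Dlx5, Gng8, Gng13, Kirrel2 and others).

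Named genes were Atf5; the 15 largest increases and the 15 largest decreases among genes past the threshold whose groups did not overlap, leaving out receptor families and provisional symbols; from each list the first 2 measured members, up to 4 members past the threshold with the largest change, or, with none past it, the member with the lowest p; and from the receptor families up to 3 per direction. For lists of neighbouring cell types and functions outside the main lists, the first 2 members stand in the result tables and are not named in the text.

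Replicate numbers were not in the model. Deviations from the group means of arrays with the same number correlated at 0.295, 0.122 and 0.234 for numbers 1, 2 and 3, each the best match of its array. The rule set in advance, that every such correlation exceed 0.1, was met, so by that rule the numbers pair the samples. This comes from the data, as the labels do not say what a number shares. A gene's deviations sum to 0 within each genotype, so these correlations depend on each other. They were not tested against chance, so the pairing stays open. The fit with the number as a block is given where it changed the call of a list or of a named gene, or moved a count by over 1.5 times.

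The procedure was tested on simulated data with the 19937 genes of this comparison. Each gene was drawn independently from a normal distribution, so the counts of called genes leave out correlation between genes. Of 67 genes changed by log2 0.5, 41 (61.2%) were called, of 67 changed by 1, 66 (98.5%), and of 66 changed by 2, 66; 6 of 179 calls were unchanged genes. In 20 runs with no change, no gene was called. A further 50 runs gave the cell division list a shared effect of single arrays and no effect of genotype. At an unadjusted p under 0.05, the preset correlation called 31 and the estimated correlation 1. All 50 runs used 1 set of drawn gene values. The array effect had a chosen size, larger than the list's measured spread (array means 10.18 to 10.36 in the knockout, 9.82 to 10.03 in the wild type). The 31 of 50 is therefore no rate of false calls for these data. The alternatives were the replicate block, quantile normalization or median centring of the arrays, filters on dim genes, the mean of probe sets, all rows, a trended and robust prior (trended only in list tests), array weights, a plain test without moderation, an adjusted p of 0.01, treat against 1.2-fold, each array left out, list tests with an estimated correlation, ranks or fry, and the mean of Y-linked genes as a covariate. Covariates for skeletal muscle and enamel genes were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.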

Results

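Gene expression was measured in the olfactory epithelium of newborn mice with and without Atf5, a gene for a transcription factor of the ATF/CREB family. Septa and turbinates of the nose were dissected on the day of birth from homozygous Atf5 knockout pups and from wild-type pups of the C57BL6 strain. Each genotype was represented by 3 samples, each pooled from 3 pups, and each sample was hybridised to 1 whole-transcript array. The 6 arrays had medians between 8.67 and 8.72 on the log2 scale. Pearson correlations over all rows were 0.992 to 0.994 for the 6 pairs of arrays of the same genotype and 0.988 to 0.992 for the 9 pairs of different genotype. No pair shared more than 12 identical values, and all arrays were kept as separate samples. The number of arrays limits the precision of every value given.

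The comparison of knockout with wild type asks which transcripts of the newborn olfactory epithelium differ when Atf5 is missing. Transcripts of mature olfactory sensory neurons fell in the knockout for 19 of 23 measured genes, and the other 4 did not pass the test. Omp (olfactory marker protein) was 4.69-fold lower (95% interval 3.79 to 5.81, n = 3 arrays per genotype). Gnal, the G protein alpha subunit of odour transduction, was 5.13-fold lower (4.56 to 5.77). Olfactory receptor genes fell in large number, 356 of 1015 measured, with a median log2 change of -0.27 over the family. Of the 27 measured genes of the integrated stress response, 6 rose, 1 fell and 20 did not pass the test. The amino acid transporter Slc7a3 was 1.72-fold higher, the folate enzyme Mthfd2 1.46-fold (1.30 to 1.65) and Shmt2 1.46-fold. By camera with the preset correlation, the mature neuron, receptor and stress lists passed (adjusted p = 2.03e-39, 1.05e-75 and 8.53e-06). With an estimated correlation no list passed (adjusted p = 0.0878, 0.0859 and 0.132 in the same order). By fry, which does not set a list against other genes, these 3 lists passed (adjusted p = 0.00188, 0.00461 and 0.0153). Of the 24 measured genes of cell division, 3 rose and 21 did not pass the test, although all 24 lay above 0. In a fit with the replicate number as a block, 21 of the 24 rose. In all, 745 of 19937 genes changed by limma, of which 100 were higher and 645 lower in the knockout. Olfactory receptors made up 55.2% of the lower ones. A fit with the replicate number as a block gave 1310 changed genes, 421 higher and 889 lower.

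Atf5 itself was lower in every knockout array than in any wild-type array. Its level was 9.46 ± 0.04 (SD, n = 3) in the knockout and 10.71 ± 0.22 (SD, n = 3) in the wild type, a log2 change of -1.25 (SE 0.10, adjusted p = 0.000499), or 2.38-fold lower (2.03 to 2.80). The labels do not say which part of the gene was removed, so it is not known whether the probe set lies inside it.

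**Figure D1:**
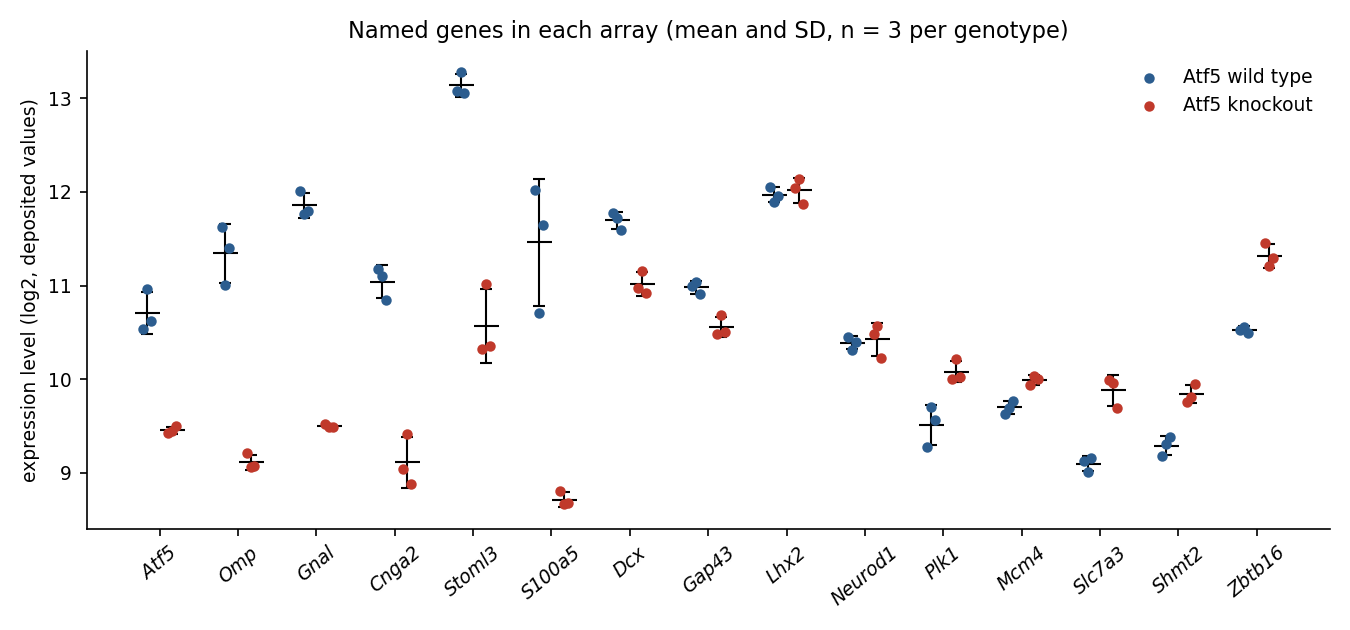
Level of 15 named genes on each array (vertical axis, log2 of the deposited values), with wild-type arrays in blue, knockout arrays in red, and the mean and SD of 3 arrays in black. Omp, Gnal, Cnga2, Stoml3 and S100a5 lie lower in every knockout array, Slc7a3, Shmt2 and Zbtb16 lie higher, and Lhx2 and Neurod1 overlap between genotypes.

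Of 23 measured genes of mature olfactory sensory neurons, 19 fell and none rose, and the remaining 4 did not pass the test. Adjusted over the list alone, 21 fell. The largest decreases were S100a5, a calcium-binding protein of these neurons, at -2.74 (SE 0.27, adjusted p = 0.000951), Stoml3, a stomatin-like protein of olfactory cilia, at -2.57 (SE 0.17, adjusted p = 0.000139), and Gnal at -2.36 (SE 0.08, adjusted p = 2.12e-06). Omp changed by -2.23 (SE 0.14) and Cnga2, a subunit of the olfactory cyclic nucleotide-gated channel, by -1.93 (SE 0.14). Faim2 (-2.11), Gng13, a G protein gamma subunit (-1.63), and Ano2, the calcium-activated chloride channel of olfactory cilia (-1.59), fell as well. The list had a median log2 change of -1.26 and moved down relative to other genes by camera (adjusted p = 2.03e-39), but not with an estimated correlation (adjusted p = 0.0878 with an estimated correlation). The mean over its members was 9.43, 9.47 and 9.35 in the knockout arrays and 10.8, 10.6 and 10.6 in the wild-type arrays. With the mean of 3 enamel genes, which was also higher in the wild type, as a covariate, the median was -0.95 and 6 members passed.

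Among olfactory receptor genes, which encode the odorant-detecting receptors, 356 fell, 2 rose and 657 did not pass the test. Adjusted over the list alone, 623 fell and 3 rose. A change below 0 was measured for 963 receptors (94.9%), and 34 were at least 2-fold lower. The largest decreases were Olfr293 (-1.44, SE 0.17), Olfr15 (-1.42, SE 0.18) and Olfr513 (-1.41, SE 0.07), and the 2 that rose were Olfr536 (0.84, SE 0.15) and Olfr330 (0.60, SE 0.09). The array median over receptors was 7.10, 7.15 and 7.13 in the knockout and 7.51, 7.42 and 7.40 in the wild type. The family moved down by camera (adjusted p = 1.05e-75; adjusted p = 0.0859 with an estimated correlation). Trace amine-associated receptors, another family of olfactory receptors, also fell in part: 5 of 13 passed (6 adjusted over the list alone), with Taar4 at -0.88 (SE 0.14), Taar7d at -0.76 (SE 0.07), Taar6 at -0.48 and Taar7b at -0.45, and a list median of -0.21 (adjusted p = 1.34e-06; adjusted p = 0.0878 with an estimated correlation). The count of lower olfactory receptors was 219 without knockout replicate 1 and 220 without wild-type replicate 1, and the call of Olfr536 ended without knockout replicate 2 or 3 or wild-type replicate 2 (highest adjusted p = 0.0774). The count of lower receptors was 160 with the mean of skeletal muscle genes as a covariate and 3 with the mean of enamel genes, with family medians of -0.23 and -0.22. These means correlated with genotype at 0.554 and -0.831, which makes the fit less precise. The lost calls therefore do not show that muscle or tooth tissue accounts for the fall.

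**Figure D2:**
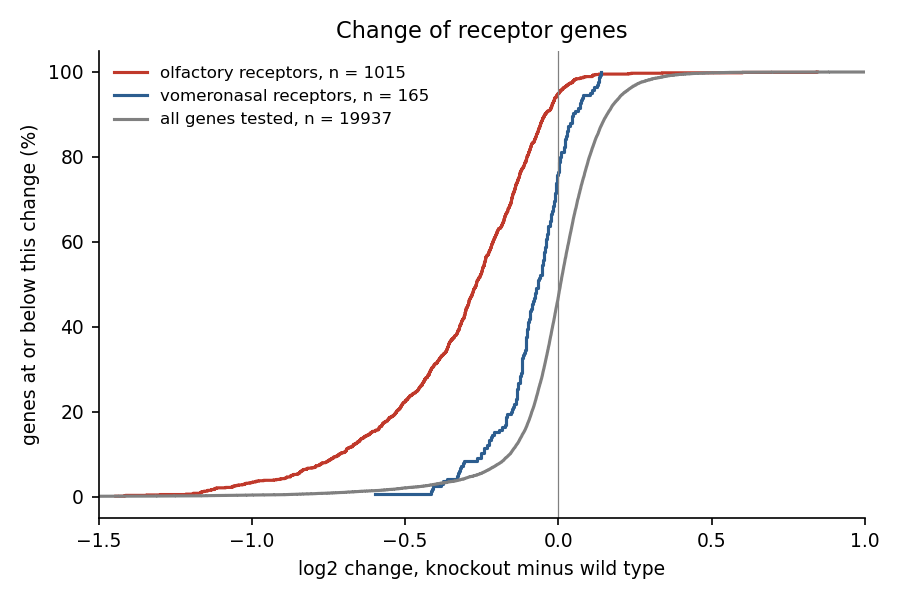
Cumulative share of genes (vertical axis, %) against log2 change of knockout minus wild type (horizontal axis) for 1015 olfactory receptors, 165 vomeronasal receptors and all 19937 genes tested. The olfactory receptor curve lies to the left, with a median of -0.27, against -0.07 for vomeronasal receptors.

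Genes of immature olfactory neurons fell in part. Dcx, a microtubule-binding protein of young neurons, was at -0.68 (SE 0.08, adjusted p = 0.00248), Gng8, a G protein gamma subunit, at -0.45 (SE 0.09) and Gap43, a growth cone protein, at -0.43 (SE 0.07), while 16 of the 19 measured genes did not pass. Adjusted over the list alone, 5 fell. The list moved down by camera (adjusted p = 0.00237; adjusted p = 0.631 with an estimated correlation), with a median of -0.10. Of 17 genes of neuronal precursors, 1 rose, the homeobox gene Dlx5 (0.33, SE 0.07), also the only one adjusted over the list alone. The proneural factors Neurog1 (0.08, SE 0.13) and Neurod1 (0.04, SE 0.09) did not pass, and the precursor list did not move by camera (adjusted p = 0.0644; adjusted p = 0.631 with an estimated correlation). With the replicate number as a block, 2 precursor genes were lower. The precursor list passed without knockout replicate 3 (0.0323) or wild-type replicate 1 (0.0263). Without wild-type replicate 1 or 2, 1 immature gene passed, and the immature list's adjusted p was 0.0545 without knockout replicate 3. The call of Dlx5 ended without any 1 array other than knockout replicate 3 (highest adjusted p = 0.119).

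Among 20 transcription factors and chromatin regulators of olfactory neurons and receptor choice, Ebf4 (-0.51, SE 0.07) and Tshz2 (-0.41, SE 0.08) fell, Dlx5 rose, and 17 did not pass. Adjusted over the list alone, 2 fell and 3 rose. Lhx2 (0.05, SE 0.08) and Emx2 (-0.00, SE 0.11), homeobox factors known to act in olfactory neuron development, did not pass, and the list did not move by camera (adjusted p = 0.461). Of 22 genes of axon guidance and adhesion, 9 fell (11 adjusted over the list alone), led by the adhesion molecules Cntn4 (-1.49, SE 0.11), Kirrel2 (-1.36, SE 0.14) and Pcdh10 (-0.97, SE 0.08) and by the ephrin Efna3 (-0.85, SE 0.16). The list moved down by camera (adjusted p = 1.26e-06; adjusted p = 0.185 with an estimated correlation). Without wild-type replicate 1 the count was 4 and Efna3 did not pass (adjusted p = 0.0718), and Tshz2 did not pass without knockout replicate 1 or 2 or wild-type replicate 1 or 2 (highest adjusted p = 0.0766).

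Of 24 measured cell division genes 3 rose, and the list moved up by camera (adjusted p = 7.22e-17), but not with an estimated correlation (adjusted p = 0.191 with an estimated correlation). Plk1, a mitotic kinase, rose by 0.57 (SE 0.11, adjusted p = 0.0203), Bub1b, a spindle checkpoint kinase, by 0.30 (SE 0.06) and Mcm4, part of the replicative helicase, by 0.29 (SE 0.06). Mki67 (0.29, adjusted p = 0.0779) and Top2a (0.33, adjusted p = 0.0772; 0.21 as the mean of its probe sets) did not pass. The median over 24 genes was 0.35, and all 24 rose when adjusted over the list alone. With the replicate number as a block, 21 members passed, Mki67 (adjusted p = 0.0312) and Top2a (adjusted p = 0.0134) among them. The count was 0 without knockout replicate 2, 1 without wild-type replicate 1 and 9 without wild-type replicate 2, Bub1b passed only without knockout replicate 3, and no call of Mcm4 was kept with any 1 array left out (adjusted p from 0.0551 to 0.17).

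Among 27 measured genes of the integrated stress response, the program driven by phosphorylation of eIF2 alpha, 6 rose, 1 fell and 20 did not pass. Adjusted over the list alone, 8 rose and 1 fell. The amino acid transporter Slc7a3 rose by 0.78 (SE 0.09, adjusted p = 0.0019), the mitochondrial folate enzyme Mthfd2 by 0.55 (SE 0.08, adjusted p = 0.00515) and the serine hydroxymethyltransferase Shmt2 by 0.55 (SE 0.08, adjusted p = 0.00507). Ppp1r15a, a phosphatase subunit that reverses eIF2 alpha phosphorylation, fell by 0.40 (SE 0.09, adjusted p = 0.0435). Ddit3 (-0.12, SE 0.08) and Trib3 (-0.13, SE 0.09), transcripts known to be induced by this response, did not pass. The list moved up by camera (adjusted p = 8.53e-06; adjusted p = 0.132 with an estimated correlation). The number that rose was 3 without knockout replicate 1, knockout replicate 2, wild-type replicate 1 or wild-type replicate 3, and Ppp1r15a passed only without wild-type replicate 3 among the settings with 1 array left out (highest adjusted p = 0.147).

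No member of the chaperone list of the endoplasmic reticulum passed, in either direction, of 24 measured. Hspa5 (-0.17, SE 0.10), Hsp90b1 (-0.14, SE 0.06) and Dnajb9 (-0.43, SE 0.11, adjusted p = 0.0665) did not pass, and the list did not move by camera (adjusted p = 0.085; adjusted p = 0.699 with an estimated correlation), with 0 calls adjusted over the list alone. With the replicate number as a block the list moved down (adjusted p = 0.0453) and Dnajb9 passed (adjusted p = 0.00601). None of 14 mitochondrial chaperones and proteases passed (camera adjusted p = 0.421), the lowest p being that of Htra2 (0.22). None of 20 genes of apoptosis and p53 signalling passed either, here or adjusted over the list alone; Bak1 was at 0.18 (SE 0.08), Bbc3 at 0.04 (SE 0.07) and Sesn1 at 0.35 (SE 0.09, adjusted p = 0.0752; 0.0163 with the block). That list was at adjusted p = 0.0488 by camera (adjusted p = 0.631 with an estimated correlation), and passed only without wild-type replicate 2 among the settings with 1 array left out (0.0205; the others 0.053 to 0.126). The chaperone list passed without knockout replicate 1 (0.00539), knockout replicate 2 (0.0449) or wild-type replicate 2 (0.0272).

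Outside the lists, the largest increase was Zbtb16, a zinc finger transcription factor, at 0.79 (SE 0.07, adjusted p = 0.000822). The histone gene H2ac4 (0.68), Depdc1a (0.56) and the mitotic kinesin Kif18b (0.47) rose, as did Nt5dc2 (0.54), Capn6 (0.54), the pyruvate dehydrogenase kinase Pdk4 (0.51), Tmem255a (0.48), the imprinted gene Peg10 (0.48), the transcript DQ267102 (0.46) and the GABA receptor subunit Gabrr1 (0.45). No gene rose by 2-fold or more, against 71 that fell by at least that much. Other large decreases were Nqo1, a quinone reductase, at -1.82 (SE 0.17), Stom, a membrane protein of the stomatin family, at -1.61 (SE 0.07), the dopamine receptor Drd2 at -1.58 (SE 0.11), and the calcium sensor Vsnl1 at -1.55 (SE 0.14). Enam at -2.47 (SE 0.51, adjusted p = 0.0301) and Amelx at -1.98 (SE 0.46, adjusted p = 0.0499), both genes of tooth enamel, fell with a wide spread: Enam was 7.49, 7.07 and 7.82 in the knockout and 10.78, 10.54 and 8.47 in the wild type. Neither passed with a trended and robust prior (adjusted p = 0.23 for Enam and 0.271 for Amelx), and Amelx did not pass after quantile normalization (0.0632), centring (0.0571), the 30th percentile or median filter (0.0521 and 0.0581) or with the mean of probe sets (0.0502). Of the 55 named genes that passed, 34 kept their call without any 1 array and 21 did not; the second group held H2ac4, Depdc1a, Capn6, Peg10, Kif18b, Gabrr1, Enam and Amelx, with highest adjusted p values of 0.104, 0.164, 0.0848, 0.166, 0.111, 0.0622, 0.131 and 0.177.

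**Figure D3:**
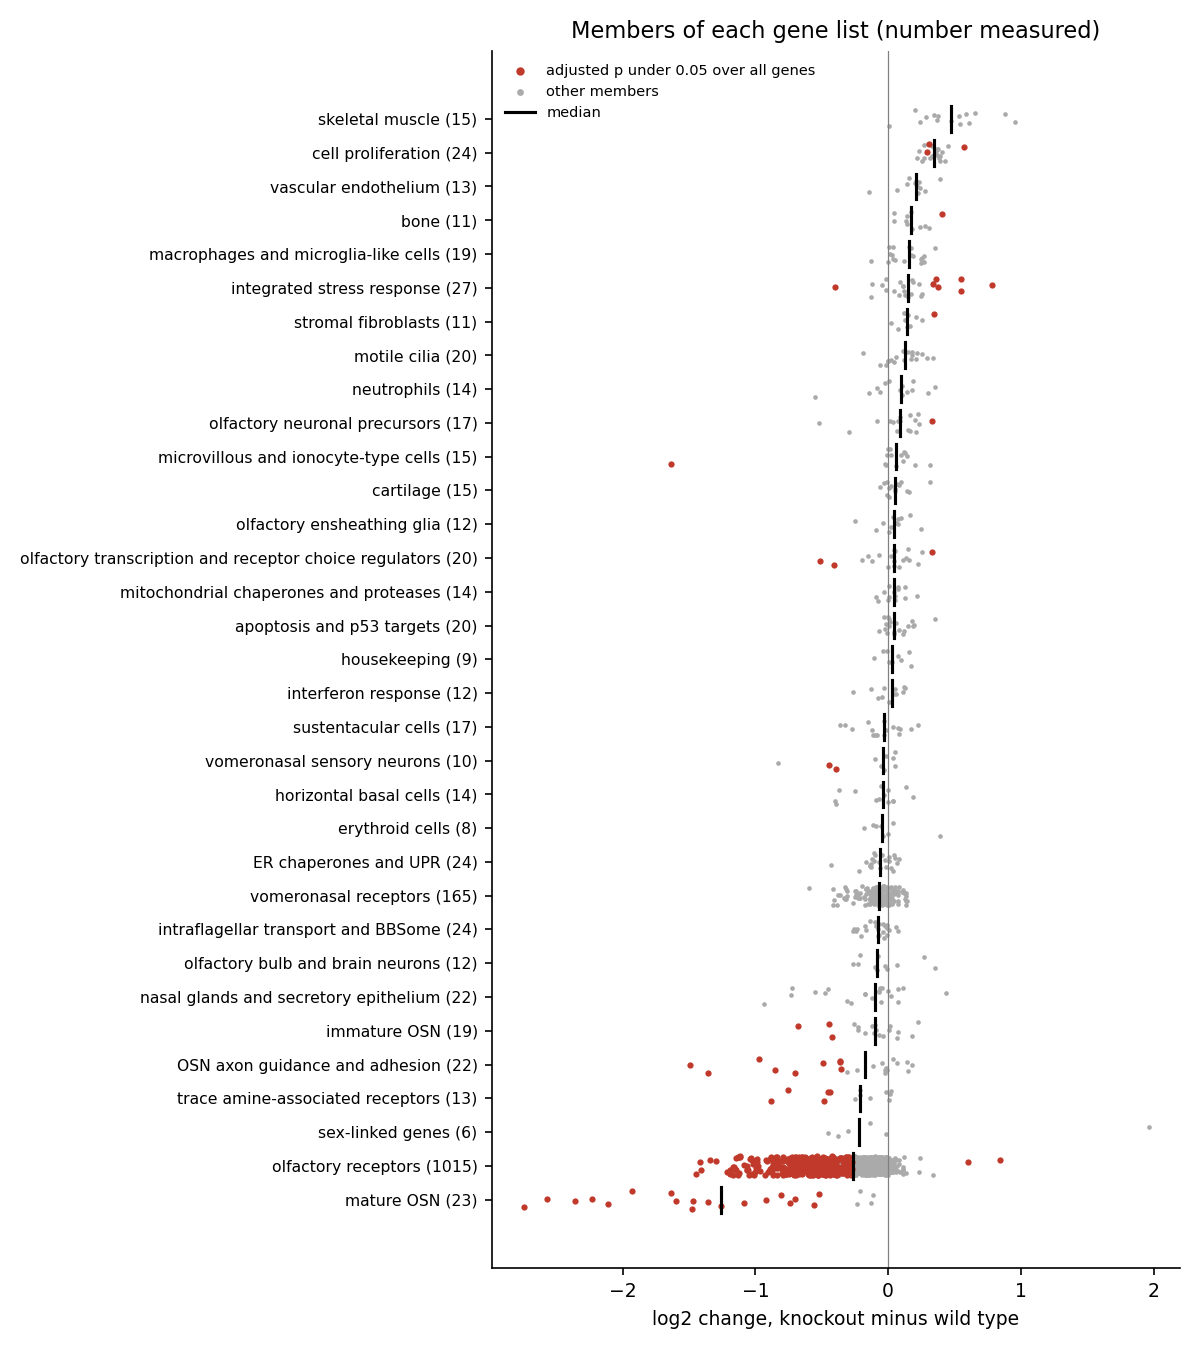
Log2 change of knockout minus wild type (horizontal axis) for every measured member of the 33 gene lists (vertical axis, number measured in brackets), with genes past the threshold in red, others in grey and the list median as a black line. Mature neuron genes have the lowest median, -1.26, and skeletal muscle genes the highest, 0.47, with none of the latter past the threshold.

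Among markers of the supporting and neighbouring cells of the epithelium, 3 genes passed the test, Gng13, Gnao1 and Gng8, all lower in the knockout. None of 17 sustentacular cell genes passed (camera adjusted p = 0.421), Cyp2g1 being at -0.36 (SE 0.09, adjusted p = 0.076; 0.0114 with the block) and Cyp1a2 at -0.33 (SE 0.38). None of 14 horizontal basal cell genes (adjusted p = 0.461, lowest p for Pax6 at 0.18), 12 ensheathing glia genes (adjusted p = 0.461; Fabp7 at -0.25, lower with the block at 0.0412, and 1 lower adjusted over the list alone) or 22 gland genes passed; the gland list was at adjusted p = 0.0488 (adjusted p = 0.699 with an estimated correlation), Obp1a, an odorant-binding protein, was at -0.73 (SE 0.26, adjusted p = 0.207; 0.0486 with the block; 0.0365 without wild-type replicate 2; -1.03 to -0.37 with 1 array left out), and 4 gland genes were lower and 1 higher with the block. Of 15 microvillous cell genes 1 fell, Gng13, which the mature neuron list also holds, and the list did not move (adjusted p = 0.422, direction up, with a median of 0.06 and a mean of -0.03). Of 10 genes of vomeronasal neurons 2 fell, Gnao1 (-0.39, SE 0.07) and Gng8, and 3 adjusted over the list alone. Gng8 also stands in the immature neuron list. The vomeronasal neuron list was at adjusted p = 0.0488 (adjusted p = 0.528 with an estimated correlation). Neither Gnao1 nor Gng8 passed without wild-type replicate 1 or 2, nor Gnao1 without knockout replicate 1. None of 165 vomeronasal receptors passed, while 8 were lower with the block, and the family had a median of -0.07 (adjusted p = 0.0017; adjusted p = 0.699 with an estimated correlation). Intraflagellar transport genes (24 measured, median -0.07, adjusted p = 0.0123) and motile cilia genes (20 measured, median 0.12, adjusted p = 0.0203) moved in opposite directions with 0 calls each, their lowest p being those of Kif17 (-0.25) and Dnaic1 (0.25); 1 motile cilia gene was higher with the block, Dynlrb2 (0.34, adjusted p = 0.329; 0.0186 with the block), named after its values were seen. Neither list moved with an estimated correlation (adjusted p = 0.699 with an estimated correlation for both). Without knockout replicate 3, adjusted p was 0.5 for intraflagellar transport, 0.458 for glands, 0.458 for vomeronasal receptors and 0.15 for vomeronasal neurons, and without knockout replicate 2 it was 0.575 for motile cilia and 0.101 for glands. Without wild-type replicate 1 these 5 lists were at 0.0703, 0.272, 0.126, 0.0653 and, for motile cilia, 0.0729, and without wild-type replicate 3 glands and vomeronasal neurons were at 0.197 and 0.0968. With array weights none of the 5 passed (intraflagellar transport 0.0692, glands 0.394, vomeronasal receptors 0.552, vomeronasal neurons 0.0951, motile cilia 0.202). By fry none passed either (0.551, 0.561, 0.561, 0.0982 and 0.551 in the same order). Motile cilia also did not pass after quantile normalization (0.0536) or with the median or 30th percentile filter (0.23 and 0.0859). Vomeronasal receptors did not pass with the 30th percentile filter (0.11), nor vomeronasal neurons after centring (0.0513) or on ranks (0.119). Glands and vomeronasal neurons did not pass with the mean of Y-linked genes as a covariate (0.0511 and 0.0613).

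Several lists of other tissues lay higher in the knockout as lists, with few calls. Endothelial genes had a median of 0.21 (13 measured, 0 calls, 1 adjusted over the list alone; adjusted p = 0.000134; adjusted p = 0.178 with an estimated correlation). Macrophage genes had a median of 0.15 (19 measured, 0 calls; adjusted p = 0.00237; adjusted p = 0.418 with an estimated correlation), with Ptprc at -0.00 (SE 0.06), Cd68 at 0.27 (SE 0.09) and Mrc1 at 0.35 (SE 0.10, adjusted p = 0.106; 0.0163 with the block). Bone genes (11 measured) and stromal genes (11 measured) had 1 rise each, the collagenase Mmp13 (0.41, SE 0.09) and the proteoglycan Lum (0.35, SE 0.08), and were at adjusted p = 0.0122 and 0.00123 (adjusted p = 0.631 and 0.132 with an estimated correlation). Mmp13 kept its call only without knockout replicate 2 (highest adjusted p = 0.122) and Lum only without knockout replicate 1 or wild-type replicate 3 (highest adjusted p = 0.173). Lum did not pass after quantile normalization (0.078), centring (0.0515) or the median filter (0.0523), with array weights (0.0593) or with the mean of Y-linked genes as a covariate (0.0809). The 15 skeletal muscle genes had a median of 0.47 with 0 calls (adjusted p = 0.000413; adjusted p = 0.647 with an estimated correlation). Their mean was 9.74, 9.89 and 10.1 in the knockout and 8.77, 9.84 and 9.72 in the wild type, with wild-type replicate 1 the lowest array, and the list was at adjusted p = 0.0553 without knockout replicate 3. The bone list was at 0.516 without knockout replicate 3, 0.0948 without wild-type replicate 2, 0.21 with array weights and 0.0846 with the median filter. Bone and muscle lists were at 0.523 by fry. The cartilage list was at 0.02 without knockout replicate 1. With the block, 3 macrophage, 2 endothelial and 2 muscle genes were higher. Neutrophil (adjusted p = 0.32), interferon (0.895), erythroid (0.558), cartilage (0.32), brain neuron (0.422), sex-linked (0.514) and housekeeping (0.447) lists did not move by camera, and none of their members passed, though 1 brain neuron gene was higher and 1 lower adjusted over the list alone. With the block, 2 neutrophil genes and 2 brain neuron genes were higher and 1 of each lower. The members of these lists with the lowest p, none past the threshold, were Ramp2 of endothelium (0.39; adjusted p = 0.00885 with the block), Myh3 of muscle (0.96; 0.0438; 0.50 to 1.37 with 1 array left out, passing at 0.0225 without wild-type replicate 2), Ngp of neutrophils (0.30; 0.0415), Ifit1 of the interferon response (-0.27; 0.0433), Alas2 of erythroid cells (0.39; 0.00982), Camk2a of brain neurons (-0.27; 0.0455) and Col11a1 of cartilage (0.14).

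**Figure D4:**
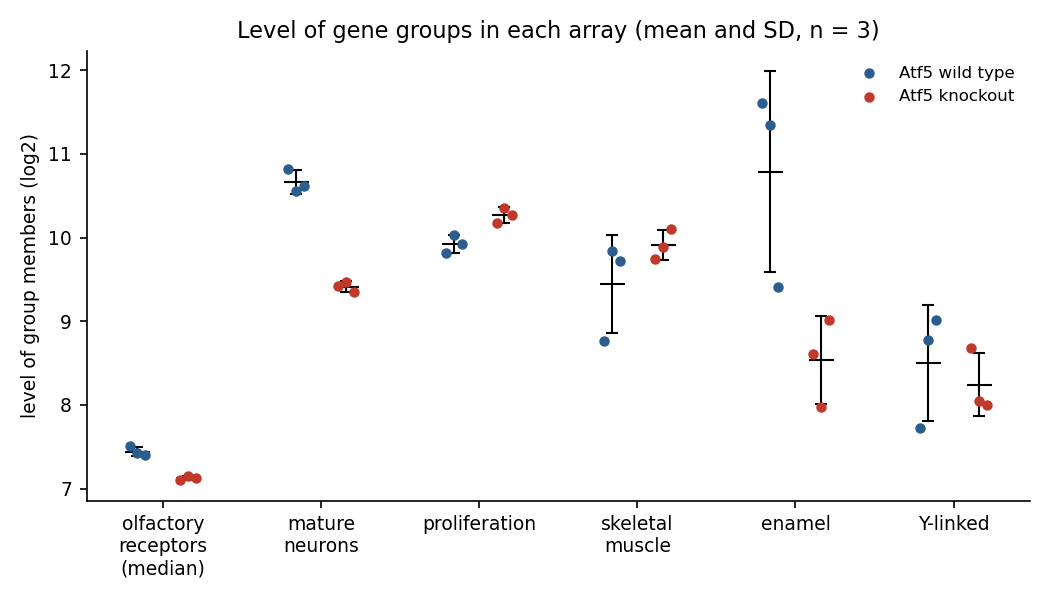
Level of 6 gene groups on each array (vertical axis, log2; the receptor group as a median, the others as means), with wild-type arrays in blue, knockout arrays in red, and the mean and SD of 3 arrays in black. Mature neuron genes separate the genotypes (knockout 9.35 to 9.47, wild type 10.6 to 10.8), and enamel and muscle genes vary widely within the wild type.

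All 745 changed genes had 3 knockout values on one side of all 3 wild-type values, as did 4204 of all genes (21.1%, where chance gives 10%). With the replicate number as a block, 1310 genes changed, 421 higher and 889 lower, including all 745, so that the higher share went from 13.4% to 32.1%. The count of higher genes was 52 without knockout replicate 1, 31 without knockout replicate 2, 27 without wild-type replicate 1 and 53 without wild-type replicate 3, and that of lower genes 403 without knockout replicate 1 and 383 without wild-type replicate 1. Further named genes lost their call after quantile normalization (Peg10 0.0789, Mcm4 0.0704), with the median filter (Peg10 0.0556, Ppp1r15a 0.053), with the 30th percentile filter (Peg10 0.0509) and with the mean of Y-linked genes as a covariate (Depdc1a 0.0541, Dlx5 0.0667, Bub1b 0.0815, Mcm4 0.0732, Ppp1r15a 0.085, Mmp13 0.0776). The unmoderated test kept 4 of the 55, Gnal, Faim2, Stom and Olfr513. With 1 array left out, none of the 55 moved by over 1.5 times, while 16 of the 34 other named genes did, and Cyp2g1 (0.0427), Dnajb9 (0.016), Ramp2 (0.0477) and Sesn1 (0.0464) each passed in 1 such setting. With the muscle mean as a covariate, 25 genes were higher and 287 lower, and with the enamel mean, 1 and 13.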

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

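The tests of level-matched receptors, of the stress genes against other cell types and of the stress genes not tied to division were chosen after the results they bear on had been seen, as were the covariates for muscle and enamel genes.

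A signal also appeared in rows of the array left out of the gene comparison because they carry no single gene symbol. In a fit over all rows, 68 of these 13120 rows passed the threshold, 23 higher and 45 lower in the knockout, a share of 0.518% against 1.54% of rows with 1 symbol. Of the 68, 36 carry several symbols, 28 of them naming olfactory receptors, and 32 carry none.

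Of the 10 ways to split the 6 arrays into 3 and 3, 1, the real one, gave as many higher genes (100), as many lower genes (645) and as many genes changed at least 2-fold (71). The highest count of any other split was 0 for each, including the 3 others that part all 3 replicate pairs. With 10 splits the share is never under 0.05. Every other split also has arrays of both genotypes on each side. A difference between genotypes then adds to the spread and lowers the count, so the counts of 0 do not measure chance.

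The lower values of olfactory receptor probe sets were weighed against 3 technical explanations. A shift of dim probe sets from normalization is argued against as the source of the whole fall. Receptors matched in level to vomeronasal receptors had a median change of -0.171, vomeronasal receptors -0.0657, and 0 of 10000 matched draws reached the latter. The vomeronasal median itself lay below that of all genes (0.007), so such a shift may supply part of the fall. The sex of the pools is argued against too, since with the mean of Y-linked genes as a covariate the median was -0.286 and 312 of 358 changed receptors passed. Whether signal near background hides part of the fall stayed open. The 338 brightest receptors fell more than the 339 dimmest (difference of medians -0.208, permutation p = 1e-05, the smallest 100000 resamples can give). A receptor hardly expressed in the wild type has little signal to lose, so this difference could also arise with no hidden fall. The matched draws and this permutation take receptors as independent of each other, so neither measures the spread between samples. Fewer mature neurons and a lower receptor level per neuron are both left open as biological explanations and were not tested, as bulk tissue does not separate them.

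Enam and Amelx were far lower in the knockout, as was Ambn in value (-2.32, adjusted p = 0.0891). The spread of Enam and Ambn was wider in the wild type (SD 1.27 and 1.56) than in the knockout (0.37 and 0.48). That of Amelx was alike (0.81 and 0.86). The mean of these 3 genes in wild-type replicate 3 (9.41) lay nearer to the highest knockout array (9.02) than to wild-type replicates 1 and 2 (11.6 and 11.3). Tooth tissue in some dissected samples is a candidate explanation. Over the 6 arrays, 6 other enamel and dentin genes had a median Pearson r of 0.617 with the mean of these 3 (exact permutation p = 0.111), a median Spearman rho of 0.657 (exact permutation p = 0.0556), and a median r of 0.914 without the 2 arrays farthest from the median, wild-type replicates 1 and 2. The single genes ranged from 0.0855 (Sp6) to 0.936 (Amtn), so the test leaves dissection and a difference between genotypes open; the arrays also split by genotype, which adds to any such correlation. That enamel mean correlated at -0.831 with genotype, so its use as a covariate makes the genotype effect less precise (variance inflation of 3.22). It may also take up part of that effect. The median change over olfactory receptors was -0.22 with it and -0.27 without it.

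The rise of 6 of the 27 integrated stress response genes was weighed against 2 changes in cell composition. A lower share of mature neurons may raise all other transcripts: the stress response list lay 0.0659 above the pooled members of 4 other cell type lists (permutation p = 0.13), which leaves this open. More dividing cells, which need serine and one-carbon units, may raise them as well: 11 members not tied to division had a median change of 0.0862. Of those 11, however, 2 rose (Chac1 at 0.36 and Ddit4 at 0.38, named after their values were seen; each passed only without knockout replicate 3 among the settings with 1 array left out) and 1 fell (Ppp1r15a), so the median over members that go both ways decides nothing. A response to the loss of Atf5 itself was not tested separately.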

How the results depend on the processing

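The muscle and enamel covariates were chosen after seeing the data. Under every alternative run for list tests, which leave out all rows, the unmoderated test, 0.01 and treat, the mature neuron, receptor, proliferation and stress lists kept their direction, and passed under all but the estimated correlation. The cause was not tested where a value moved, except that filters test fewer genes, all rows test more, and a left-out array leaves fewer samples.

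With the replicate block, 421 genes were higher (100 without it) and chaperones reached 0.0453; among list tests it turned only the interferon list (0.913), which passed in neither fit. It ended no call of the 745 genes and changed no other list call; named genes that gained a call with it, and those that lost one in settings other than left-out arrays, are given with the results. Named genes also gained 4 calls by quantile normalization, 3 with the trended prior and 6 with weights.

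Higher genes numbered 60 above the median level, 42 over all rows, 291 with array weights, 2 by the unmoderated test, 15 at 0.01, 2 by treat, 61 with the Y covariate, 25 with muscle and 1 with enamel, and 27 to 127 with each array left out. Lower genes (645) numbered 226 and 358 with the median and 30th percentile filters, 359 over all rows, 12 unmoderated, 317 at 0.01, 145 by treat, 287 with muscle and 13 with enamel, and 383 to 584 with an array left out. Those at least 2-fold lower (71) were 38 above the median level, 6 unmoderated, 44 with muscle and 12 with enamel, and 49 to 95 with an array left out; 2-fold higher was 1 over all rows, with muscle and with enamel, and 0 to 1 with an array left out. Atf5 stayed at -1.25 without moderation and -1.16 with enamel, and passed in neither; it was -1.34 to -1.13 with an array left out.

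List tests are adjusted p values. Chaperones (0.085) reached 0.011 by quantile, 0.0058 and 0.0243 with the median and 30th percentile filters, 0.0344 on ranks and 0.0255 with enamel (0.00539 to 0.73 with an array left out). Apoptosis (0.0488) was 0.0724 by quantile, 0.0513 centred, 0.348 and 0.254 filtered, 0.0692 weighted, 0.631 with an estimated correlation, 0.235 by fry, 0.0566 on ranks, 0.0511 with Y, 0.182 with muscle and 0.127 with enamel (0.0205 to 0.126). Precursors (0.0644) were 0.0445 weighted, 0.0344 on ranks and 0.0122 with muscle (0.0263 to 0.147). With an estimated correlation, mature neurons were at 0.0878, receptors 0.0859, immature neurons 0.631, proliferation 0.191, stress 0.132 and macrophages 0.418. By fry 8 lists passed, at 0.00188 to 0.0383. They were mature neurons, olfactory receptors, trace amine-associated receptors, axon guidance, stress, stroma, endothelium and proliferation. Immature neurons were at 0.235 by fry and macrophages at 0.158. Immature neurons were at 0.0914 with muscle (3.78e-05 to 0.0545) and macrophages at 0.463 with enamel.

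Directions turned only for genes and lists that passed neither as reported nor where they turned. These were Ptprc (0.0136 by quantile, 0.00418 centred, 0.0134 with Y, -0.0383 to 0.0232 with an array left out), Emx2 (0.00162 centred, 0.0647 weighted, -0.0931 to 0.13), Neurog1 (-0.0506 to 0.24), Neurod1 (-0.0333 to 0.14), Lhx2 (-0.0140 to 0.12) and Cyp1a2 (-0.75 to 0.0503). Among lists they were regulators (0.882 above the median level, 0.204 to 0.829), microvillous cells (0.783 above the median level, 0.551 by fry, 0.189 to 0.806), glia (0.732 above the median level, 0.328 to 0.887), neutrophils (0.695 at the 30th percentile, 0.129 to 0.498), interferon (0.637 at the 30th percentile, 0.894 weighted, 0.4 to 0.887), sustentacular cells (0.246 with muscle, 0.0956 to 0.772), erythroid (0.236 to 0.806), brain neurons (0.222 to 0.903) and sex-linked genes (0.793 with Y, 0.0605 to 0.978).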

Other observations

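The tests of class and of genes next to Atf5 were planned before the results were seen, but the class test within level was chosen after them; the glucocorticoid list was written after Zbtb16, Pdk4 and Hif3a had been noticed and before its other members were looked at.

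Zbtb16 and Pdk4, which rose in the knockout, and Hif3a, which did not pass (0.49, adjusted p = 0.0995), are known to respond to glucocorticoids or fasting. In a list of 19 other such genes, 3 rose, Klf9 (0.43, SE 0.09), Tsc22d3 (0.44, SE 0.10) and Per1 (0.35, SE 0.08), and none fell. Each of these 3 lost its call in at least 4 of the 6 settings with 1 array left out (highest adjusted p = 0.0947, 0.136 and 0.145). Adjusted over the list alone, 6 rose, and 14 of 19 lay above 0, with a median of 0.14. Fkbp5 (0.36, adjusted p = 0.0826) and Errfi1 (0.29, adjusted p = 0.0846) did not pass. A glucocorticoid or fasting response in the pups is a hypothesis that stayed open: the list's camera p was 0.000166 with the preset correlation and p = 0.19 with an estimated correlation of 0.319.

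Class I receptors, the evolutionarily older class, and class II receptors did not separate in their change over all levels. The medians were -0.24 for 118 class I receptors and -0.27 for 883 class II receptors, a difference of 0.0368 (permutation p = 0.16). Class I receptors were brighter (median level 7.60 against 7.24), and compared within 3 groups of like level the median difference was 0.0648 (permutation p = 0.043), the groups being at 0.0648, 0.0647 and 0.105 from dimmest to brightest. These permutations take receptors as independent of each other, so a smaller decrease of class I receptors stays open. By level, the 339 dimmest receptors had a median of -0.16 and 17.4% of them fell, against -0.30 and 38.5% of the 338 in the middle and -0.37 and 49.4% of the 338 brightest.

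None of the 50 measured genes that neighbour Atf5 in assembly GRCm38.p6, 25 on each side, passed the threshold in limma, which allows a share of up to 7.11% (exact binomial limit). Elsewhere 3.74% of genes passed (Fisher's exact test, 2-sided, p = 0.265). Sequence of a donor strain kept around the targeted allele may still be present, as the test could not tell these shares apart.

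The pools appear to differ in sex-linked transcripts. Xist was 12.70, 13.19 and 13.17 in the knockout arrays and 13.25, 12.53 and 7.39 in the wild-type arrays. The Y-linked gene Eif2s3y was 9.86, 8.56 and 8.48 in the knockout and 7.91, 10.04 and 10.31 in the wild type.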
